A study of Mus musculus with 24 samples.

How the data were processed

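The samples were eosinophils of the mouse bone marrow in 4 stages of maturation, from mice in steady state or after daily injections of 400 ng of IL-33 for 7 days, with 3 libraries per group and 24 in all. Per the labels' protocols, cells were pooled from 3 mice per sample, cells carrying Ly6G, CD90.2, NK1.1 or CD45R were first removed magnetically, and the stages were then sorted on CD29, F4/80, Siglec-F, CD55, CD117, Pir-A/B and CD200R3. Libraries were made with SMART-Seq v4 and Nextera XT, per the labels' protocols, a method that does not mark the strand, so reads of a gene and of an overlapping or antisense partner cannot be told apart. The design text of the series calls the triplicates biological.

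The deposited file of each library holds a whole-number count of reads per gene, and these were used as raw counts. Each file had 24982 gene symbols and 2 entries that name no gene, for reads assigned to no feature and for ambiguous reads. These 2 entries stayed out of library sizes and tests. Reads with no feature made up 21.6% ± 3.69 (SD, n = 12) of all counted reads in steady state and 12.5% ± 2.5 under IL-33, and ambiguous reads 1.73% to 2.6% per library. Per the submitters' processing notes, STAR 2.6.1a, the build mm10 and DESeq2 were used. The counting tool, its strand setting and the gene annotation are not given in the sources used here. Positions were taken from GENCODE M21 on GRCm38 (mm10) by symbol, which matched 24490 of the 24982 symbols (98%). Mitochondrially encoded genes were not analysed here.

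Gene counts per library ranged from 8335138 to 14909453. Replicates of a group differed by far more than counting error, with a chi-square per degree of freedom between 21 and 130 over pairs, so no library was a copy of another. Precision was therefore set by the spread between the 3 libraries of a group, estimated over all 8 groups together. Counting error matters only for genes with few reads, for which a group with no counts was set to a floor of 3 counts over the group and a group with 1 to 3 counts was given a ratio with its exact 95% counting interval.

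Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with edgeR's filter by group, which left 12743, libraries were scaled by the trimmed mean of M values (TMM), and 1 quasi-likelihood fit of the 8 groups over all 24 libraries gave every comparison: 3 steps between stages in each condition, IL-33 against steady state in each stage and averaged over the stages, the difference of each step between conditions and the joint test of any difference of the IL-33 effect among stages. Adjusted p-values follow Benjamini and Hochberg over the genes tested, with a threshold of 0.05, and the standard error (SE) of a log2 fold change is its size over the square root of F. Levels are CPM scaled by TMM. Fixed gene lists, 38 in number of which 37 had at least 3 tested members (between 5 and 52), were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and comparisons of a family, and again with a correlation estimated per list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

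The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. A gene was named if it passed the adjusted threshold, the 3 libraries of 1 group all lay above the 3 of the other, which chance gives in 10% of genes, and at least 1 group averaged 20 CPM. Genes were then ranked by fold change, with up to 6 rises and 6 falls per steady state step and per stage comparison, 3 and 3 per IL-33 step and per interaction (without the overlap rule) and 10 and 10 for the average, for which no overlap was asked in at least 3 of the 4 stages. Symbols of predicted genes, Riken clones, small RNAs and receptor segments were passed over. From each list up to 4 members with the smallest adjusted p were added, and a panel of 15 genes was kept whatever its result. Results of some single genes that the rule names are not reported here. Genes with near-identical copies (Ear genes, Bcl2a1 copies, Pirb, Lilra6 and histocompatibility genes) are uncertain, as reads may be split between copies.

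Whether replicate numbers pair libraries was checked from the correlation of their deviations from the group means, with 0.1 as the bar for each of 3 pairs. It was passed from stage I to II in steady state (0.12 to 0.3), from III to IV in steady state (0.11 to 0.22) and from I to II and II to III under IL-33 (0.15 to 0.24 and 0.13 to 0.24). It was not passed from II to III in steady state (lowest 0.06), from III to IV under IL-33 (lowest 0.05) or between conditions. In every step between stages, also those below the bar, all 6 libraries lay closest to the library of their own number. Between conditions 0 to 5 of 6 did. The pairing comes from the data, since the labels give only the numbers.

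The alternatives were DESeq2 1.42.0, limma-voom with sample weights, relative log expression factors, library totals alone, TMM without granule genes and the 20 most abundant genes, no filter, a filter of at least 10 CPM in 3 libraries, a fit of the compared groups only, the replicate number as a block, and leaving out each library. Leaving out the 4 steady state libraries numbered 3, called the third steady state pool here, and adding the share of unassigned reads as a covariate were chosen after seeing the data. The labels do not say whether libraries of a number share mice. That share was lower in every IL-33 library than in any steady state library, so this covariate is confounded with the condition. The script was tested on simulated counts in which 50 genes were changed per fold size. Changes of 2, 4 and 8-fold were recovered in 12%, 54% and 84% of genes for stage I of IL-33 against steady state (12475 genes), 26%, 64% and 84% for stage II (12474), 8%, 68% and 78% for stage III (12493) and 8%, 62% and 76% for stage IV (12470). For the steady state steps the shares were 10%, 62% and 70% from I to II (12488 genes), 12%, 72% and 66% from II to III (12460) and 6%, 60% and 76% from III to IV (12471). False calls numbered between 1 and 8 per comparison. All genes outside these and a shifted list were left unchanged, so at most 96 genes were called. The real comparisons mostly called more, which loosens the adjusted threshold. The IL-33 steps, the interactions and the average were not simulated.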

Results

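Messenger RNA was counted per gene in eosinophils of the mouse bone marrow, sorted by flow cytometry into 4 successive stages of maturation named I to IV. The cells came either from mice in steady state or from mice injected with interleukin 33 (IL-33), a cytokine released by damaged tissue that drives eosinophilia, the accumulation of eosinophils. The injected mice received 400 ng into the peritoneum each day for 7 days. Each of the 8 groups of stage and condition held 3 libraries, 24 in all, every library made from cells pooled from 3 mice. Gene counts summed to between 8335138 and 14909453 per library, and between 11666 and 13576 genes had at least 1 count. Among the 12743 genes tested, the first principal component of log expression carried 41.5% of the variance.

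Some measures of the libraries differed between conditions or set libraries apart. Reads assigned to no gene made up 21.6% ± 3.69 (SD, n = 12) of the counted reads in steady state and 12.5% ± 2.5 (SD, n = 12) under IL-33. The difference of -9.12 percentage points had p = 0.1 in an exact two-sided permutation test that moved the 4 libraries of a condition and number together, the smallest value its 20 relabellings can give. The mean over the 4 libraries of a number was at most 13.8% under IL-33 and at least 19.8% in steady state. Since the highest IL-33 library (16.6%) lay below the lowest steady state library (17.8%), a fit with this share as a covariate is confounded with the condition, and calls that it ends are not shown to come from the share. All 4 steady state libraries numbered 3 stood apart on Jun and Atf3, genes induced early after cell stress, and on the Y-linked gene Ddx3y. They are called the third steady state pool here, though the labels do not say that they share mice. Jun lay between 3331 and 5018 CPM in them and between 875 and 2142 CPM in the other 20 libraries, and Atf3 between 164.6 and 1063 CPM against at most 51.97 CPM. Ddx3y ranged from 174.1 to 384.4 CPM in that pool and from 35.26 to 86.31 CPM elsewhere, while Fos overlapped, at 3189 to 4468 CPM against 1058 to 3373 CPM.

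Genes of a fixed panel differed in level along the stages. Epx (chromosome 11, 87864000 to 87875536, GRCm38), which encodes eosinophil peroxidase of the specific granules, went in steady state from 14100 ± 1757 CPM (SD, n = 3) in stage I to 2702 ± 1075 CPM in stage III and 21.8 ± 4.17 CPM in stage IV. Under IL-33 it stood at 16580 ± 3500, 13780 ± 1998 and 5801 ± 1210 CPM in the same stages. Prg2 (chromosome 2, 84980461 to 84983632), which encodes the major basic protein of the granule, was at 10580 ± 2742 CPM in stage III and 471 ± 227 CPM in stage IV in steady state, against 11170 ± 477 and 10500 ± 1252 CPM under IL-33. The proliferation gene Mki67 (chromosome 7, 135689784 to 135716361) was at 359 ± 140 CPM in stage II and 60.5 ± 17.7 CPM in stage III in steady state, and at 373 ± 36.5 CPM in stage III under IL-33. Ccr3 (chromosome 9, 124021972 to 124031689), the eotaxin receptor, went from 3.03 ± 3.28 to 1991 ± 365 CPM over the stages in steady state and from 4.75 ± 1.88 to 1544 ± 128 CPM under IL-33. Itgb1, which encodes the sort marker CD29, passed the test in none of the 6 steps between stages and none of the 4 stage comparisons of IL-33 with steady state, with group means between 104 and 239 CPM. Cebpe, a transcription factor gene of granulocytes, stood at 493 ± 191 CPM in stage I and 461 ± 172 CPM in stage IV in steady state and at 672 ± 193 and 910 ± 81.8 CPM under IL-33, and Siglecf, which encodes a sort marker, at 307 ± 142 and 464 ± 140 CPM and at 271 ± 69.3 and 710 ± 88.5 CPM.

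**Figure D1:**
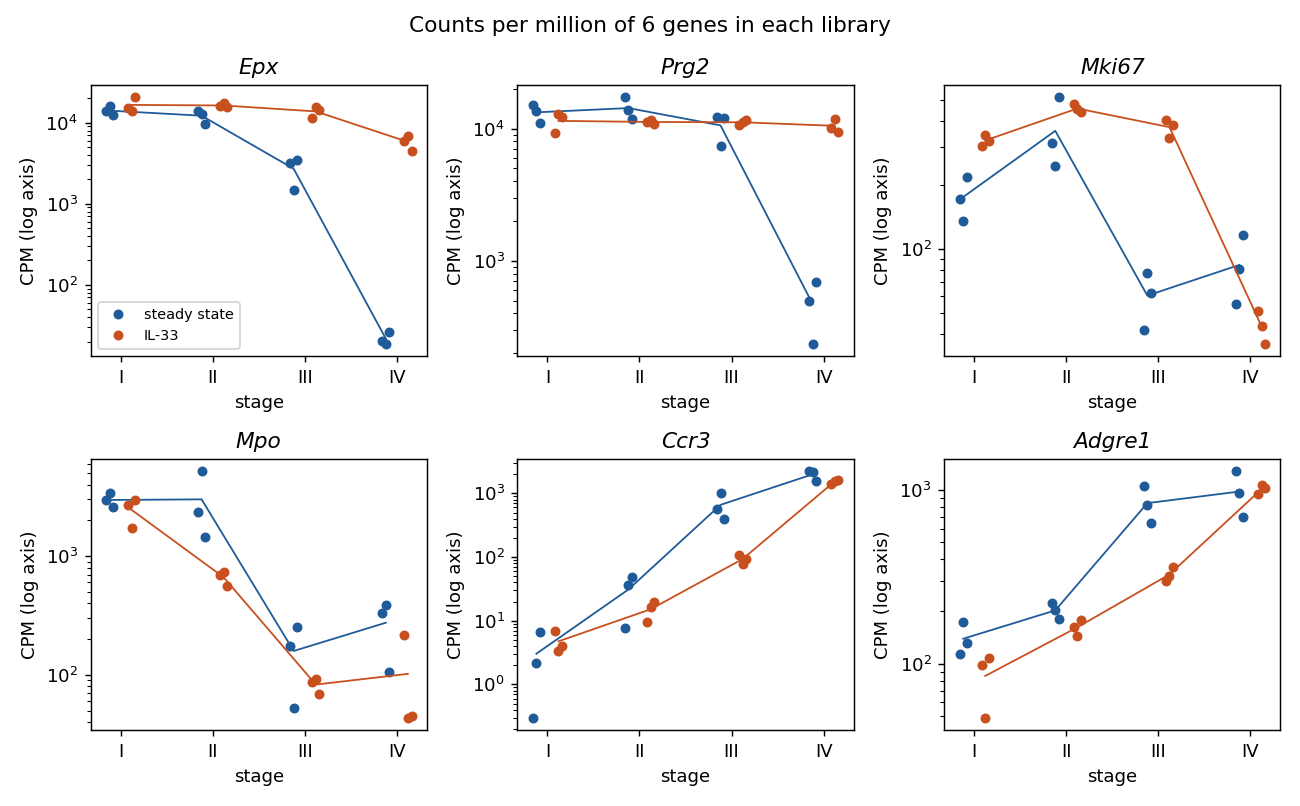
CPM on a log axis of Epx, Prg2, Mki67, Mpo, Ccr3 and Adgre1 in the 24 libraries by stage and condition, with a point per library and lines joining the means of 3. Epx reached a mean of 21.8 CPM in stage IV in steady state and 5801 CPM under IL-33, and Mki67 60.5 and 373 CPM in stage III.

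Which genes changed as eosinophils matured in steady state was asked step by step. From stage I to stage II, genes of adhesion and migration rose: 10 of 25 members passed the test, all higher, and 16 adjusted over the list alone. Alox15, a lipoxygenase abundant in eosinophils, rose 8.62-fold (log2 3.11, SE 0.30, edgeR adjusted p = 3.28e-06), the chemokine receptor gene Ccr1 8.04-fold (log2 3.01, SE 0.33, edgeR adjusted p = 7.32e-06) and the leukocyte integrin gene Itgb2 2.83-fold (edgeR adjusted p = 0.000402). The list passed camera, a test of a list against all other genes, at adjusted p = 3.15e-16, and at adjusted p = 0.0171 with an estimated correlation. Of 30 eosinophil surface receptors 7 rose, 7 beside 1 lower adjusted over the list alone, among them Cd9 2.55-fold and Ccr3 9.94-fold (log2 3.31, SE 0.63), with an adjusted p = 0.086 with an estimated correlation. Of 10 genes for markers used in the sort 4 rose, 5 adjusted over the list alone (adjusted p = 0.0503 with an estimated correlation), with Pirb 8.66-fold higher and Cd200r3 15.5-fold, a call that limma-voom did not make. Reads of Pirb are uncertain, since it has near-identical copies. Pirb, Siglecf and Adgre1 stand in both the receptor and the sort marker list. The oxidative defence list had 7 of 20 members higher, 9 adjusted over the list alone, with Hmox1, the heme oxygenase gene, 7.49-fold (log2 2.91, SE 0.45) higher and an adjusted p = 0.0503 with an estimated correlation. In the list of G2 and mitosis, 4 of 28 genes rose and 15 adjusted over the list alone, with the cyclin gene Ccnb2 2.26-fold higher and an adjusted p = 0.086 with an estimated correlation.

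Markers of other cell types moved in the same step. Of 17 monocyte and macrophage markers 8 rose, 11 adjusted over the list alone, with Csf1r, the receptor of the macrophage growth factor, 9.97-fold (log2 3.32, SE 0.34) higher and the protease gene Ctss 6.65-fold (adjusted p = 0.0171 with an estimated correlation). Without the third steady state pool 5 of the 17 rose. Of 16 neutrophil markers 2 rose, among them Retnlg 8.49-fold, and 8 adjusted over the list alone (adjusted p = 0.261 with an estimated correlation). Serpinb2, which encodes an inhibitor of plasminogen activators, rose 54.5-fold (log2 5.77, SE 0.78, edgeR adjusted p = 0.000106), Rap1gap2 29.9-fold, Ms4a4a 15.2-fold and Lilra6 14.1-fold. Atmin fell 4.35-fold (log2 -2.12, SE 0.46).

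By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 620 of the 12743 genes differed between stages II and I, 73.5% of them higher and 164 lower. With library totals as the scaling the split was 292 higher and 227 lower, and the median of all genes lay at -0.16 on the log2 scale. With the replicate number as a block, which pairs these libraries, 1069 genes passed, and in a fit of these 6 libraries alone 21 did, among them Alox15, Ccr1, Csf1r, Hmox1, Itgb2 and Pirb but not the other genes named for this step. The count was 307, 289 and 339 without the stage I libraries 1 and 2 and the stage II library 3, and Ccnb2 was no longer called without the stage I library 2 or the third steady state pool.

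From stage II to stage III in steady state the cell cycle genes fell together. All 28 genes of G2 and mitosis fell, with a median log2 fold change of -2.75, and 26 of 27 genes of S phase and DNA replication, with a median of -2.83, the same numbers adjusted over each list alone. Top2a, the topoisomerase of dividing cells, fell 9.62-fold (log2 -3.27, SE 0.30, edgeR adjusted p = 1.16e-07), the kinesin gene Kif23 10.5-fold and the replicative helicase genes Mcm3 7.3-fold (log2 -2.87, SE 0.24) and Mcm7 6.17-fold. Both lists held with an estimated correlation, at adjusted p = 0.0171 and 0.000719. Of 25 ribosome biogenesis genes 23 fell, 24 adjusted over the list alone, including Mybbp1a 8.29-fold and Nop56 5.25-fold (adjusted p = 0.0343 with an estimated correlation). Of 24 genes for folding in the endoplasmic reticulum 15 fell, 16 adjusted over the list alone, among them the chaperone gene Calr 8.12-fold (log2 -3.02, SE 0.38) and the regulator of the unfolded protein response Xbp1 3.36-fold (adjusted p = 0.253 with an estimated correlation). All 5 primary granule genes, which mark early neutrophil and monocyte precursors, fell: Mpo 18.9-fold (log2 -4.24, SE 0.64), Ms4a3 28.2-fold, Ctsg 17.8-fold, Prtn3 14.4-fold and Elane, also 5 adjusted over the list alone (adjusted p = 0.133 with an estimated correlation).

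Receptor, adhesion and oxidative defence genes rose in that step. Of 30 eosinophil surface receptors 15 rose, also 15 adjusted over the list alone, with Ccr3 21.3-fold (log2 4.41, SE 0.63, edgeR adjusted p = 1.43e-05) and Adgre1, which encodes the sort marker F4/80, 4.14-fold (log2 2.05, SE 0.27) higher (adjusted p = 0.0503 with an estimated correlation). Of 25 adhesion genes 15 rose and 1 fell, the same adjusted over the list alone, with the selectin ligand gene Selplg 3.37-fold and the integrin gene Itgb7 6.08-fold higher (adjusted p = 0.171 with an estimated correlation). Of 20 oxidative defence genes 13 rose and 1 fell, the same adjusted over the list alone, including Nqo1 8.24-fold and the catalase gene Cat 3.82-fold (adjusted p = 0.117 with an estimated correlation), and 8 rose without the third steady state pool. The cytokine gene Il4 rose 5.38-fold (log2 2.43, SE 0.26) and Gata1, the transcription factor that specifies the lineage, 2.32-fold. The progenitor genes Kit and Cd34 fell 8-fold and 5.12-fold. Kit encodes CD117, which was used in the sort. Epx fell 4.51-fold (log2 -2.17, SE 0.27), and it and Prg3 were the 2 of 7 granule genes that passed, also 2 adjusted over the list alone.

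Markers of basophils, mast cells and neutrophils went both ways between stages II and III. Of 13 basophil and mast cell markers 6 fell and 1, Il4, rose, the same adjusted over the list alone (adjusted p = 0.496 with an estimated correlation). The mast cell protease gene Cpa3 fell 14.9-fold and the IgE receptor gene Ms4a2 17.1-fold. Of 16 neutrophil markers 2 rose and 4 fell, 2 and 5 adjusted over the list alone (adjusted p = 0.925 with an estimated correlation). Pbld1 was at least 278-fold higher in stage III against a floor of 3 counts over the stage II libraries, which had none. The netrin receptor gene Unc5c was 1190-fold higher (95% counting interval 212 to 46900) and Adgrg6, an adhesion receptor gene, 154-fold (log2 7.27, SE 0.78) higher. Chit1, a chitinase gene, was at least 200-fold lower, the growth factor gene Fgf3 710-fold (127 to 28100) and the cadherin gene Cdh1 251-fold lower (85.7 to 1220). Such floors and intervals cover counting error only. In all, 4405 genes differed by edgeR's test, 2188 higher and 2217 lower, and with library totals as the scaling 1349 were higher and 3057 lower, with a median of all genes of -0.33. In a fit of these 6 libraries alone 1965 genes passed.

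From stage III to stage IV in steady state the granule genes fell. All 7 members passed, also 7 adjusted over the list alone, with a median log2 fold change of -4.49 (camera adjusted p = 2.78e-45, and adjusted p = 4e-04 with an estimated correlation). Epx fell 124-fold (log2 -6.96, SE 0.34, edgeR adjusted p = 3.15e-12), Prg3 31.9-fold, Prg2 22.5-fold (log2 -4.49, SE 0.31) and the eosinophil ribonuclease gene Ear6 32.5-fold. Reads of the Ear genes are uncertain, since these genes are near-identical copies. The list took 1.64% ± 0.379 (SD, n = 3) of the gene counts in stage III and 0.0846% ± 0.0378 in stage IV. Of 20 genes of cholesterol synthesis 9 fell, 14 adjusted over the list alone, including Msmo1 4.9-fold and Fdps 3.38-fold (adjusted p = 0.0442 with an estimated correlation). Of 27 genes of autophagy and lysosome 8 fell, 9 adjusted over the list alone, among them Lamp2 2.49-fold, and 5 without the third steady state pool (adjusted p = 0.13 with an estimated correlation).

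Markers of other cells moved in the same step. Of 5 primary granule genes Prtn3 rose 3.97-fold (log2 1.99, SE 0.44), and 4 were higher adjusted over the list alone, with a median log2 fold change of 1.59 (camera adjusted p = 0.00318, and adjusted p = 0.302 with an estimated correlation). Each stage IV library stood at 271% or more of the stage III mean of this list. Of 13 basophil and mast cell markers 3 fell and 1, Il4, rose 1.99-fold, also 3 and 1 adjusted over the list alone (adjusted p = 0.529 with an estimated correlation). Il4 was no longer called without the third steady state pool, in a fit of these 6 libraries alone or with the unassigned share as a covariate. Of 6 megakaryocyte and platelet markers 1 fell, 2 adjusted over the list alone (camera adjusted p = 0.00867, and adjusted p = 0.103 with an estimated correlation). Of 16 neutrophil markers 1 fell, 1 beside 1 higher adjusted over the list alone (adjusted p = 0.96 with an estimated correlation).

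From stage III to IV the growth factor receptor gene Fgfr1 rose 629-fold (log2 9.30, SE 0.89, edgeR adjusted p = 1.01e-06), the integrin gene Itgax 143-fold, Retnla, a resistin-like protein gene, 72.3-fold (log2 6.18, SE 0.70), the transcription factor gene Batf3 55-fold and the chemokine gene Ccl9 10.3-fold. Il17rb, which encodes a receptor chain for interleukin 25, fell 55.2-fold (log2 -5.79, SE 0.45) and Alas1 of heme synthesis 4.56-fold, and Qrfpr was at least 306-fold lower. In edgeR's test 1176 genes differed, 38.5% of them higher and 723 lower, and with library totals as the scaling 652 were higher and 491 lower, with a median of all genes of 0.17. The count was 719 without the stage IV library 2, 245 in a fit of these 6 libraries alone, where Fdps and Msmo1 were no longer called, and 518 with the share of unassigned reads as a covariate, an alternative added after seeing the data that also ended the call of Fdps.

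Under IL-33 the early steps called few single genes, while several lists passed. From stage I to stage II the 5 primary granule genes were lower as a list, with a median log2 fold change of -1.94 (camera adjusted p = 2.72e-13, and adjusted p = 0.0179 with an estimated correlation). Of them Prtn3 fell 5.41-fold, and 4 were lower adjusted over the list alone. The 30 eosinophil surface receptors were higher as a list, with 1 member passing and 7 adjusted over the list alone (adjusted p = 0.0179 with an estimated correlation). The 10 markers used in the sort, which define the stages, were higher with 1 passing and 5 adjusted over the list alone (adjusted p = 0.0279 with an estimated correlation). The member that passed was Pirb in both lists, which also share Siglecf and Adgre1, so the rise of the receptors may partly be set by the sort. Of 10 eicosanoid synthesis genes Alox15 rose 3.81-fold (log2 1.93, SE 0.29), and 2 were higher adjusted over the list alone (adjusted p = 0.0378 with an estimated correlation). None of 11 markers of stem and multipotent progenitors passed, nor adjusted over the list alone, but the list was lower with a median of -0.93 (adjusted p = 0.0279 with an estimated correlation), and its camera adjusted p went from 0.00144 to 0.063 without the stage I library 1. Adhesion genes had 3 of 25 members higher, 7 adjusted over the list alone (adjusted p = 0.0578 with an estimated correlation). In edgeR's test 12 genes passed, 10 higher and 2 lower, with 821 at an unadjusted p under 0.05, and Adam19, a membrane protease gene, rose 6.94-fold (log2 2.79, SE 0.38, edgeR adjusted p = 0.0026). With the replicate number as a block, which pairs these libraries, 24 genes passed, and 41 by DESeq2, 905 by limma-voom, 41 without the third steady state pool and 4 with the share of unassigned reads as a covariate. The count was 3 without the stage II library 1 or the stage I library 2, and 2 without the stage II library 2, the stage I library 3 or the stage II library 3. Adam19 kept its call without each of these 5 libraries, Prtn3 lost it without each, and with the covariate, and Alox15 lost it without the stage I library 2.

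From stage II to stage III under IL-33 11 genes passed, all higher, with 684 at an unadjusted p under 0.05. That number is near the share of 0.05 of all genes tested that no change would give. Retnlg, the neutrophil marker, rose 7.54-fold (log2 2.91, SE 0.51, edgeR adjusted p = 0.025), the lymphotoxin gene Ltb 3.45-fold and Csf1r 3.11-fold. The surface receptors were higher as a list, with none of 30 passing and 9 adjusted over the list alone (adjusted p = 0.00815 with an estimated correlation), and the sort markers with none of 10 passing and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0279 with an estimated correlation). The primary granule genes were lower with none of 5 passing and 4 adjusted over the list alone (median -2.08, adjusted p = 0.0179 with an estimated correlation). None of 25 ribosome biogenesis genes passed, nor adjusted over the list alone, but the list was lower with a median of -0.69 (adjusted p = 0.0179 with an estimated correlation). None of the 27 genes of S phase passed, nor adjusted over the list alone, with a median log2 fold change of -0.40, and the list was lower by camera (adjusted p = 1.19e-07, and adjusted p = 0.0697 with an estimated correlation). The same held for the 28 genes of G2 and mitosis, with a median of -0.19 (camera adjusted p = 0.0357, and adjusted p = 0.558 with an estimated correlation), and the camera call of this list ended at 0.194, 0.0819 and 0.123 without the stage II library 2 or the stage III libraries 1 and 3. DESeq2 called 111 genes in this step and limma-voom 1089. The replicate block, which pairs these libraries, gave 93, and a fit of these 6 libraries alone 678. Leaving out a library gave 0 for the stage II libraries 1, 2 and 3 and the stage III library 1, 1 for the stage III library 3 and 5 for the stage III library 2, and Csf1r lost its call in each. Retnlg and Ltb kept theirs only without the stage III library 2.

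From stage III to stage IV under IL-33 the cell cycle genes fell. Of the 28 genes of G2 and mitosis 27 fell, with a median log2 fold change of -3.42, and 26 of 27 of S phase, with a median of -3.05, also 27 and 26 adjusted over each list alone. Top2a fell 12.4-fold (log2 -3.63, SE 0.30, edgeR adjusted p = 3.41e-08), the cyclin genes Ccna2 16.9-fold and Ccnb2 9.35-fold, and Mcm3 22.5-fold (log2 -4.49, SE 0.26). Both lists held with an estimated correlation, at adjusted p = 0.00407 and 0.000824. Of 25 ribosome biogenesis genes 20 fell, 21 adjusted over the list alone, with Nolc1 15.5-fold and the RNA polymerase I subunit gene Polr1b 77.8-fold lower (adjusted p = 0.0279 with an estimated correlation). Of 24 folding genes 16 fell, also 16 adjusted over the list alone, including Calr 8.13-fold and Canx 4.07-fold (adjusted p = 0.151 with an estimated correlation). Epx fell 2.38-fold (log2 -1.25, SE 0.26) and was the 1 of 7 granule genes that passed, also 1 adjusted over the list alone, while the list took 3.24% ± 0.255 (SD, n = 3) of the gene counts in stage III and 1.8% ± 0.201 in stage IV.

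Receptor and defence genes rose in the same step. Of 30 eosinophil surface receptors 17 rose, also 17 adjusted over the list alone, among them Ccr3 16.6-fold (log2 4.05, SE 0.62, edgeR adjusted p = 3.41e-05) and Cd9 3.58-fold (adjusted p = 0.0258 with an estimated correlation). Of 16 antigen presentation genes 9 rose, 10 adjusted over the list alone, with H2-D1 2.56-fold and B2m 2.28-fold higher (adjusted p = 0.0179 with an estimated correlation). Of 29 interferon-stimulated genes 13 rose, also 13 adjusted over the list alone, including Isg15 10.1-fold and Xaf1 13.5-fold (adjusted p = 0.0697 with an estimated correlation). Of 13 genes targeted by interleukins 4 and 13 through STAT6, 5 rose, also 5 adjusted over the list alone, with Retnla 55.8-fold and Ccl9 31.4-fold higher (adjusted p = 0.0279 with an estimated correlation). Neutrophil markers rose beside them, 8 of 16, and 8 with 1 lower adjusted over the list alone, with Retnlg 10-fold and S100a8 10.7-fold higher (adjusted p = 0.49 with an estimated correlation). The primary granule list stood at 566%, 72% and 158% of its stage III mean in the stage IV libraries 1, 2 and 3. The serotonin transporter gene Slc6a4 rose 466-fold and Fgfr1 272-fold, and the DNA polymerase gene Pole fell 69.3-fold. This step called 3710 genes in edgeR's test, 1669 higher and 2041 lower, against 1099 higher and 2597 lower with library totals as the scaling, when the median of all genes was -0.21. With limma-voom 6620 genes passed.

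**Figure D2:**
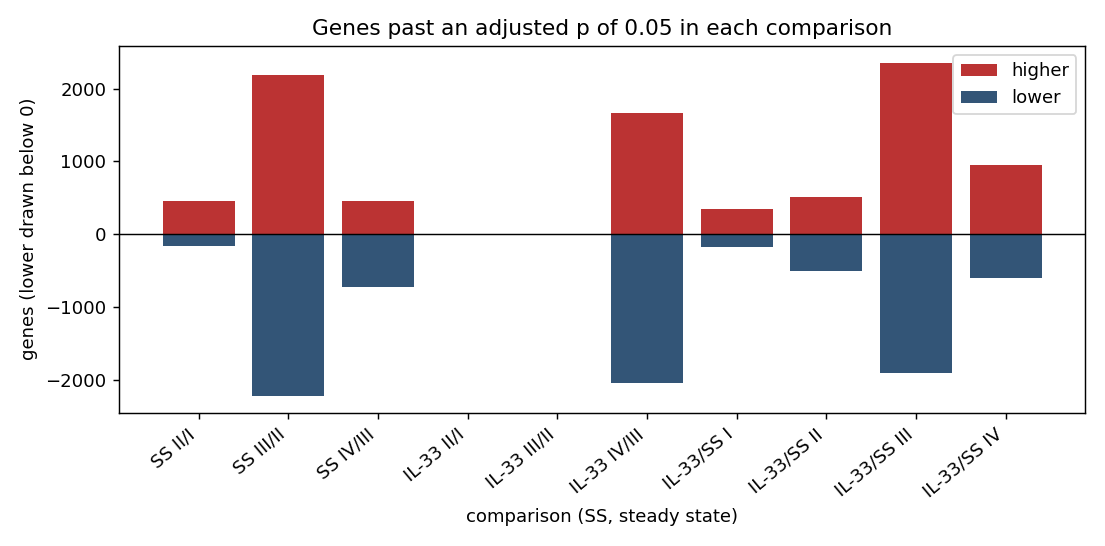
Numbers of genes called higher (bars above 0) and lower (bars below 0) by edgeR's test in the 6 steps between stages and the 4 comparisons of IL-33 with steady state, 3 libraries per group. The step from II to III called 4405 genes in steady state and 11 under IL-33, and the step from III to IV 1176 and 3710. The spread of each gene was estimated over all 24 libraries, so each count depends on the other groups too. In fits of only the libraries compared, the step from II to III called fewer genes in steady state and more under IL-33.

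What IL-33 changed within each stage was asked next. In stage I, the lipase gene Lipg was 116-fold (log2 6.86, SE 1.15, edgeR adjusted p = 0.00139) higher under IL-33, Crhbp, which encodes a binding protein of a stress hormone, 42.5-fold (log2 5.41, SE 0.57), the survival gene Bcl2a1a 72.9-fold and the receptor gene Nrp1 22.5-fold. Apoe, the apolipoprotein gene, was 10.1-fold (log2 -3.34, SE 0.34, edgeR adjusted p = 3.54e-06) lower and Cd72 35.5-fold. Of 28 genes of G2 and mitosis 11 were higher, 19 adjusted over the list alone, with Ccnb2 2.35-fold and Cdca8 2.07-fold higher (adjusted p = 0.0567 with an estimated correlation). Of 29 interferon-stimulated genes 7 were lower, 8 adjusted over the list alone, including Irf7 3.98-fold and Usp18 6.12-fold (adjusted p = 0.0567 with an estimated correlation). Of 20 STAT5 target genes 5 were higher, 7 adjusted over the list alone, led by Socs2, an inhibitor of cytokine signalling, 18.7-fold (adjusted p = 0.0928 with an estimated correlation). Cd55, which encodes a sort marker, was 2.77-fold (log2 1.47, SE 0.23) higher.

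In stage I 518 genes differed by edgeR's test, 345 higher and 173 lower. With library totals as the scaling 150 were higher and 224 lower, with a median of all genes of -0.16, and with a stricter filter on low counts 49.6% of the calls were higher. The count was 149 and 161 without the steady state libraries 2 and 3, and 880, 109 and 233 without the IL-33 libraries 1, 2 and 3. Cd72, Cdca8, Irf7 and Usp18 were no longer called without the IL-33 library 2, Ccnb2, Cdca8 and Usp18 without the steady state library 2, Irf7 and Usp18 without the steady state library 3, and Usp18 without the IL-33 library 3. Cdca8, Irf7 and Usp18 were also not called in a fit of these 6 libraries alone, in which 328 genes passed. With the share of unassigned reads as a covariate, which is confounded with IL-33 and was added after seeing the data, 17 genes passed, among them Apoe and Tspo2, which was 20.9-fold higher, and none of the other genes named for stage I.

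In stage II markers of other myeloid cells were lower under IL-33. Of 16 neutrophil markers 11 were lower, 14 adjusted over the list alone, with Fcnb 50.5-fold (log2 -5.66, SE 1.02, edgeR adjusted p = 0.00141) and Chil3 15.9-fold lower (adjusted p = 0.0928 with an estimated correlation). Of 17 monocyte and macrophage markers 9 were lower, 12 adjusted over the list alone, among them Ctss 11.8-fold and Irf8 8.34-fold (adjusted p = 0.0074 with an estimated correlation). Primary granule genes were lower in 4 of 5, also 4 adjusted over the list alone, with Prtn3 13-fold, Elane 27.3-fold, Ctsg 4.56-fold and Mpo 4.53-fold (adjusted p = 0.0928 with an estimated correlation). Of 16 antigen presentation genes 7 were lower, 12 adjusted over the list alone, including H2-DMa 6.43-fold and B2m 1.8-fold (adjusted p = 0.00314 with an estimated correlation). Of 29 interferon-stimulated genes 9 were lower, 14 adjusted over the list alone beside 1 higher, with Xaf1 29.8-fold and Irf7 4.96-fold lower (adjusted p = 0.0122 with an estimated correlation).

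Genes seldom counted in steady state were present in stage II under IL-33. Bex1 was at least 330-fold higher, the complement genes Hc and C7 at least 314-fold and at least 262-fold, and Crhbp 126-fold (log2 6.98, SE 0.63, edgeR adjusted p = 1.01e-06). Cyp11a1 (chromosome 9, 58006411 to 58027023), which encodes the side-chain cleavage enzyme of steroid synthesis, was 19-fold (log2 4.25, SE 0.50) higher and the transcription factor gene Gata2 8.07-fold. The chitinase gene Chit1 was 434-fold lower (95% counting interval 120 to 3590), the histamine receptor gene Hrh2 93.6-fold and Csf3r, the receptor of the granulocyte growth factor, 42.7-fold (log2 -5.42, SE 1.08). In stage II 1023 genes differed by edgeR's test, 517 higher and 506 lower, and with a stricter filter on low counts 31% of the calls were higher. The count was 656 without the steady state library 3 and 580, 381 and 571 without the IL-33 libraries 1, 2 and 3. Mpo was no longer called without any of these IL-33 libraries or without the steady state library 2, and Ctsg without the latter or the IL-33 library 1. With the share of unassigned reads as a covariate 310 genes passed, and Ctsg did not.

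In stage III the cell cycle genes were higher under IL-33. All 28 genes of G2 and mitosis passed, with a median log2 fold change of 3.18, and 25 of 27 of S phase, with a median of 2.71, also 28 and 25 adjusted over each list alone. Top2a was 12.1-fold (log2 3.60, SE 0.30, edgeR adjusted p = 3.93e-08) higher, Tpx2 of the mitotic spindle 14.3-fold, Mki67 6.17-fold (log2 2.62, SE 0.29) and Mcm3 6.99-fold. Both lists held with an estimated correlation, at adjusted p = 0.0074 and 0.00314. Of 25 ribosome biogenesis genes 22 were higher, also 22 adjusted over the list alone, including Mybbp1a 12.6-fold (adjusted p = 0.0467 with an estimated correlation). Of 24 folding genes 18 were higher and 1 lower, the same adjusted over the list alone, with Calr 11.7-fold (log2 3.55, SE 0.39) and Xbp1 4.58-fold higher (adjusted p = 0.117 with an estimated correlation). Epx was 5.1-fold (log2 2.35, SE 0.27, edgeR adjusted p = 1.15e-06) higher, and 2 of 7 granule genes passed, also 2 adjusted over the list alone.

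Receptor genes and markers of other cells were lower in stage III under IL-33. Of 30 eosinophil surface receptors 14 were lower and 2 higher, 16 and 2 adjusted over the list alone, with Ccr3 7.09-fold (log2 -2.83, SE 0.58) and Cd9 4.04-fold lower (adjusted p = 0.122 with an estimated correlation). Of 16 neutrophil markers 14 were lower, also 14 adjusted over the list alone, among them Retnlg 11.9-fold and S100a8 15.2-fold (adjusted p = 0.327 with an estimated correlation). Of 29 interferon-stimulated genes 14 were lower and 1 higher, 16 and 1 adjusted over the list alone, with Xaf1 30.7-fold and Isg15 9.89-fold lower (adjusted p = 0.0894 with an estimated correlation). Of 16 antigen presentation genes 9 were lower, also 9 adjusted over the list alone, including H2-D1 3.15-fold (adjusted p = 0.0122 with an estimated correlation). Basophil and mast cell markers went the other way, 9 of 13 higher and 2 lower, also 9 and 2 adjusted over the list alone, with Cyp11a1 294-fold (log2 8.20, SE 0.62), Ms4a2 66.3-fold and Gata2 32.5-fold higher (adjusted p = 0.117 with an estimated correlation). The basophil protease genes Prss34 and Mcpt8, chosen after their values were seen, had means of 17.3 ± 13 and 97 ± 14.9 CPM (SD, n = 3) under IL-33 against 182 ± 55 and 105 ± 32.2 CPM in steady state.

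The cation transporter gene Slc22a3 was at least 788-fold higher in stage III, Hs3st1 of heparan sulfate synthesis at least 344-fold and the steroid dehydrogenase gene Akr1c18 3330-fold (95% counting interval 598 to 132000). Fcrl1 was 182-fold lower, Lrg1 104-fold and the thrombospondin gene Thbs1 75.3-fold (log2 -6.24, SE 1.14). By edgeR's test 4256 genes differed, 2357 higher and 1899 lower, and with library totals as the scaling 3049 were higher and 1220 lower, with a median of all genes of 0.27. With the share of unassigned reads as a covariate 2224 genes passed.

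In stage IV the granule genes were higher under IL-33. All 7 passed, also 7 adjusted over the list alone, with a median log2 fold change of 4.62 (camera adjusted p = 1.82e-36, and adjusted p = 0.0014 with an estimated correlation). Epx was 267-fold (log2 8.06, SE 0.35, edgeR adjusted p = 3.58e-13) higher, Prg2 22.3-fold (log2 4.48, SE 0.31), Prg3 34.7-fold and Ear6 29.3-fold. Of 13 basophil and mast cell markers 9 were higher and 1 lower, 9 and 2 adjusted over the list alone (adjusted p = 0.0014 with an estimated correlation). Cyp11a1 stood at 1072 ± 265 CPM (SD, n = 3) against 1.41 ± 0.547 CPM, 773-fold (log2 9.60, SE 0.65) higher, Gata2 was 65.7-fold higher and Cpa3 15.9-fold. Prss34 and Mcpt8 had means of 5.96 ± 7.74 and 39.3 ± 12.6 CPM under IL-33 against 182 ± 170 and 130 ± 128 CPM. Cd200r3, which basophils also carry and which was used in the sort, was 37.8-fold (log2 5.24, SE 0.58) higher. Of 20 cholesterol synthesis genes 11 were higher, also 11 adjusted over the list alone, including Fdps 4.52-fold and the sterol regulator gene Srebf2 4.19-fold (adjusted p = 0.0363 with an estimated correlation). Of 20 STAT5 target genes 8 were higher, also 8 adjusted over the list alone beside 1 lower, with the kinase gene Pim2 13.3-fold, Socs2 398-fold and the survival gene Bcl2 7.79-fold higher (adjusted p = 0.0567 with an estimated correlation).

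Of 27 S phase genes 8 were lower in stage IV under IL-33, 12 adjusted over the list alone, including Mcm3 2.43-fold and Prim1 2.99-fold (adjusted p = 0.236 with an estimated correlation), and 5 without the third steady state pool. Plxdc2 was at least 333-fold higher, the cadherin gene Cdh17 at least 224-fold and Nov, a matricellular protein gene, 1970-fold (95% counting interval 354 to 78000). Apoe was 16.2-fold (log2 -4.02, SE 0.35, edgeR adjusted p = 5.99e-08) lower, the cytokine gene Il15 16.2-fold and Thbs1 42.5-fold. In stage IV 1550 genes differed by edgeR's test, 953 higher and 597 lower, and with library totals as the scaling 748 were higher and 749 lower, with a median of all genes of -0.15. The count was 802 without the IL-33 library 2, 2693 by limma-voom and 189 with the share of unassigned reads as a covariate, in which Fdps, Srebf2 and Thbs1 were no longer called.

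**Figure D3:**
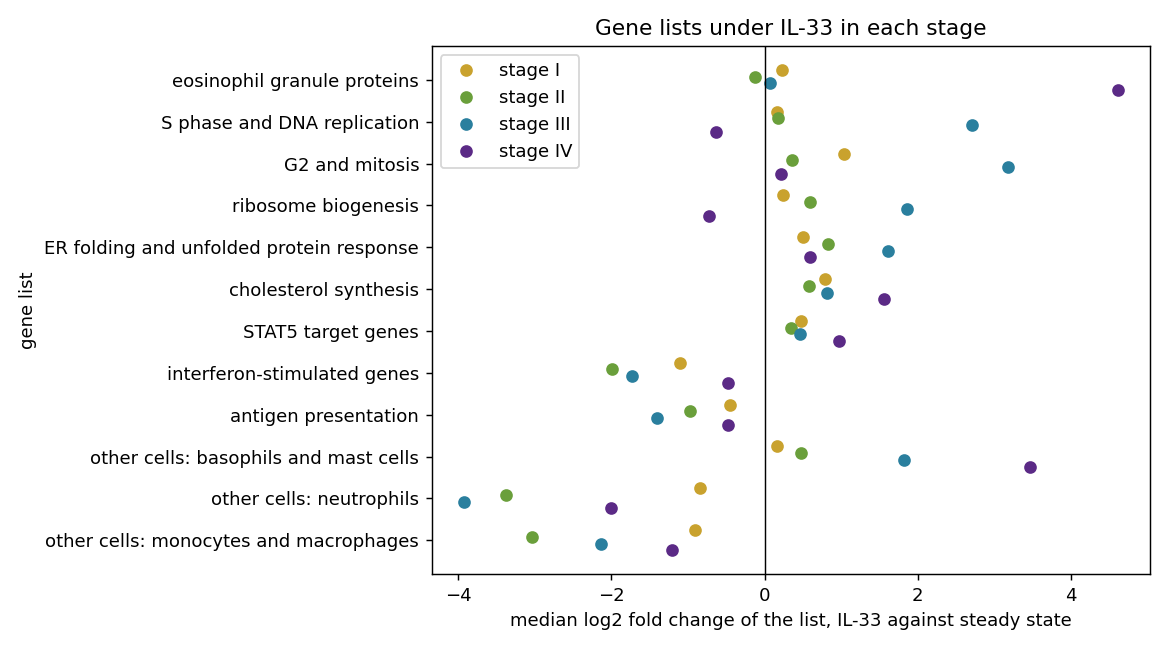
Median log2 fold change of IL-33 against steady state over the tested members of 12 fixed gene lists in stages I to IV, 3 libraries per group. The median of the G2 and mitosis list was 3.18 in stage III, and that of the granule list 4.62 in stage IV.

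Averaged over the 4 stages, Crhbp was 301-fold (log2 8.24, SE 0.40, edgeR adjusted p = 3.09e-12) higher under IL-33, Cyp11a1 80.3-fold (log2 6.33, SE 0.28), Socs2 70.5-fold, the lipoxygenase gene Alox8 146-fold and Bcl2a1a 34.6-fold, though reads of the Bcl2a1 copies are uncertain. From counts summed over the 12 libraries of each condition, Hc was 2190-fold higher (95% counting interval 606 to 18100). That ratio is not the mean of the stage differences given for the other genes, and its interval covers counting error only. Il1rl1, which encodes the IL-33 receptor, was 2.05-fold (log2 1.03, SE 0.16) higher and Cd55 2.24-fold, and Il5ra, the interleukin 5 receptor gene, 1.61-fold lower. Apoe was 13.1-fold (log2 -3.71, SE 0.17, edgeR adjusted p = 3.49e-13) lower, Thbs1 35.8-fold, Rbpms 25.9-fold and Tlr2, a receptor for bacterial lipoproteins, 11-fold. The fit counts the 4 libraries of a condition and number as independent, though they deviated together in most steps between stages. The SE and p-values of averaged effects may therefore be too small. Of 28 genes of G2 and mitosis 26 were higher, also 26 adjusted over the list alone, with Top2a 2.61-fold higher (adjusted p = 0.0229 with an estimated correlation). Of 29 interferon-stimulated genes 19 were lower and 1 higher, 22 and 1 adjusted over the list alone, with Rtp4 9.74-fold lower (adjusted p = 0.0229 with an estimated correlation). Of 16 antigen presentation genes 11 were lower, 12 adjusted over the list alone, with B2m 1.65-fold lower (adjusted p = 0.00999 with an estimated correlation).

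Markers of other cells moved beside these lists in the average. Of 13 basophil and mast cell markers 8 were higher and 3 lower, the same adjusted over the list alone, with Gata2 14.6-fold higher (adjusted p = 0.02 with an estimated correlation). Gata2 also stands in the fixed list of eosinophil lineage transcription factors, and Cd200r3 of this list was used in the sort. The basophil protease genes Prss34 and Mcpt8 had no higher means under IL-33 in stages III and IV, as given above. Of 16 neutrophil markers 14 were lower, 14 beside 1 higher adjusted over the list alone, with Fcnb 13.4-fold lower (adjusted p = 0.134 with an estimated correlation). Of 17 monocyte and macrophage markers 12 were lower and 2 higher, 13 and 2 adjusted over the list alone, with Ctss 5.29-fold lower (adjusted p = 0.0648 with an estimated correlation). Of 9 erythroid markers 7 were lower, also 7 adjusted over the list alone (adjusted p = 0.0648 with an estimated correlation), and 5 without the third steady state pool.

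Further lists of the averaged effect depended on the third steady state pool. Of 34 NF-kB target genes 15 were lower and 4 higher, 17 and 4 adjusted over the list alone (adjusted p = 0.69 with an estimated correlation), against 9 lower and 9 higher without that pool. Of 19 immediate early and heat shock genes 8 were lower and 1 higher, 8 and 2 adjusted over the list alone (adjusted p = 0.686 with an estimated correlation), against 4 lower and 5 higher without that pool. Of 12 dendritic cell markers 8 were lower, 9 adjusted over the list alone (adjusted p = 0.132 with an estimated correlation), and 4 without that pool. By edgeR's test, which counts libraries of 1 number as independent, 4855 genes differed on average, 2724 higher and 2131 lower. With the share of unassigned reads as a covariate, which is confounded with IL-33, 258 genes passed, among them Crhbp, Cyp11a1, Socs2, Alox8, Bcl2a1a, Hc, Apoe, Rbpms, Top2a and Rtp4, and Il1rl1, Cd55, Il5ra, Thbs1, Tlr2 and Ctss were no longer called.

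Whether a step between stages differed between the conditions was tested as an interaction. In the step from II to III, 25 of 28 genes of G2 and mitosis differed, all higher under IL-33, and 28 adjusted over the list alone, and 19 of 27 of S phase, 26 adjusted over the list alone. The difference was 3.04 on the log2 scale for Top2a. Both lists held with an estimated correlation, at adjusted p = 0.00371 and 0.000737. Of 25 ribosome biogenesis genes 4 differed, 14 adjusted over the list alone (adjusted p = 0.0992 with an estimated correlation), and 16 without the third steady state pool, when the list passed (adjusted p = 0.0289 with an estimated correlation). In the step from III to IV all 7 granule genes differed, higher under IL-33, also 7 adjusted over the list alone (adjusted p = 0.0115 with an estimated correlation), with Epx at 5.71 and Prg2 at 4.40 on the log2 scale. In the same step 27 of 28 genes of G2 and mitosis and 23 of 27 of S phase differed in the other direction, 28 and 24 adjusted over each list alone (adjusted p = 0.015 and 0.000737 with an estimated correlation).

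For the step from I to II the 17 monocyte and macrophage markers were lower under IL-33 as a list, with a median difference of -1.77 on the log2 scale (adjusted p = 0.0201 with an estimated correlation), as were the 16 antigen presentation genes, with a median of -0.75 (adjusted p = 0.0451 with an estimated correlation). Of their members 2 and 0 were lower adjusted over each list alone. Without the third steady state pool the adjusted p with an estimated correlation was 0.0786 and 0.15. No gene passed edgeR's interaction test for this step, with 967 at an unadjusted p under 0.05. DESeq2 called 103 genes there, limma-voom 37 and edgeR with the replicate block 41, and leaving out the steady state stage II library 2, stage I library 3 or stage II library 3 gave 5, 12 and 12. For the step from II to III 842 genes differed, 572 higher under IL-33 and 270 lower, and with library totals as the scaling 892 and 115, with a median of all genes of 0.31. That count was 540, 500 and 471 without the IL-33 stage II libraries 1, 2 and 3, and 4.6e+02 without the IL-33 stage III library 2. It was 1391 with the replicate block, 1364 by DESeq2 and 1664 without the third steady state pool. For the step from III to IV 2388 genes differed, 1075 higher and 1313 lower, and with library totals as the scaling 539 and 1904, with a median of all genes of -0.40. Any difference of the IL-33 effect among the 4 stages was found in 2264 genes.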

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

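The weighing tests of the 3 patterns and the counts over other splits of the samples were chosen after the result was seen, whereas the interaction tests had been planned. The step from stage II to III differed between conditions in 842 genes, the step from III to IV in 2388, and the IL-33 effect differed among the 4 stages in 2264.

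Transcripts of mitosis and, less fully, of S phase stayed high in stage III under IL-33. The S phase list stood at 69.9% to 79.1% of its stage II mean. It was lower in that step by camera (adjusted p = 1.19e-07, and adjusted p = 0.0697 with an estimated correlation). Stage II cells carried into the stage III sort would bring all their transcripts, but primary granule genes stood at no more than 20.9% of their stage II mean in any IL-33 stage III library, while the G2 and mitosis list stood at 83.1% to 96.6%. Stage II cells with few primary granule transcripts, which mark early neutrophil and monocyte precursors, stay open. An offset between conditions common to every stage would cancel in the step, yet 25 of 28 G2 and mitosis genes differed in it. With the share of unassigned reads as a covariate 25 of 28 were still called higher in stage III, and the median log2 fold change went from 3.18 (median SE 0.40) to 2.61 (0.47). The primary granule values, from 5 genes, argue against an even carry-over of stage II cells. A common offset alone would not give steps that differ. Those steps are the pattern itself, however, so they are no separate test of an offset. The covariate is confounded with IL-33, so a cause behind the unassigned share stays open. A slower exit from the cell cycle under IL-33 may be a biological explanation, found and tested on the same data.

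Granule protein transcripts stayed high in stage IV under IL-33. Stage III cells carried into the stage IV sort would bring cell cycle transcripts, but the G2 and mitosis list stood at no more than 12.1% of its stage III mean, against 46.7% to 98.8% for the granule list. Stage III cells that had left the cycle stay open. A common offset would cancel in the step, yet 7 of 7 granule genes differed in it. That difference is the pattern itself, so it is no separate test of an offset. With the share of unassigned reads as a covariate 4 of 7 were called, as the median SE went from 0.37 to 0.60 and the median log2 fold change from 4.62 to 4.32. The trend with that share within groups did not account for the size of the difference. As the share is confounded with IL-33, a cause behind it stays open.

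Neutrophil marker transcripts were lower under IL-33 although cells carrying Ly6G had been depleted. As a list they did not pass camera with an estimated correlation in the average (adjusted p = 0.134). Fewer neutrophil lineage cells of the same composition would keep the ratio of Ngp to Camp, 2 granule genes of neutrophil precursors, alike in both conditions of a stage. That ratio differed most in stage III, at 32.7 in steady state and 169 under IL-33, 5.17 times apart. Its libraries did not overlap there, but replicates of 1 group lay up to 7.49 times apart, so a lower share of such cells stays open. Cells of changing maturity stay open as well, since 2 of 16 markers rose and 4 fell from stage II to III in steady state, and a difference in the cells sorted may lie behind these markers.

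Genes whose step from II to III was higher under IL-33 were Hs3st1 (edgeR adjusted p = 0.000655), at a mean of 38.7 CPM in IL-33 stage III and 0 in steady state stage III, Slc22a3 (adjusted p = 0.00506), at 90.2 and 0 CPM, and Cdh1 (adjusted p = 5.11e-05), at 17.8 and 0.119 CPM. Cdh1 had stood at 28.6 CPM over the steady state stage II libraries, so its difference came with a fall in steady state. In the other direction Unc5c (edgeR adjusted p = 0.000613) stood at 2.61 and 38.4 CPM, Adgrg6 (adjusted p = 0.000299) at 8.42 and 22.4 CPM and P2ry10 (adjusted p = 0.000198) at 28.4 and 95.1 CPM. For the step from III to IV, also higher under IL-33, Qrfpr (edgeR adjusted p = 0.000313) stood at 3.21 CPM in IL-33 stage IV and 0 in steady state stage IV, Fam160a1 (adjusted p = 0.0025) at 20.4 and 0 CPM and Chil5 (adjusted p = 0.000225) at 32.2 and 7.43 CPM. Qrfpr had stood at 31 CPM over the steady state stage III libraries, so its difference likewise came with a fall there. That step was lower under IL-33 for Hs3st1 (edgeR adjusted p = 0.000457), which went from 38.7 to 2.52 CPM under IL-33 and from 0 to 1.13 CPM in steady state. It was lower as well for Slc45a3 (edgeR adjusted p = 0.00171), from 24.3 to 0.482 CPM and from 0.0381 to 1.04 CPM, and Slc22a3 (adjusted p = 0.0376), from 90.2 to 17.5 CPM and from 0 to 0.806 CPM. Among the panel, the IL-33 effect differed among the stages for Epx (edgeR adjusted p = 6.2e-11), Prg2 (2.55e-07), Mki67 (2.66e-05), Ccr3 (0.0243), Cd34 (0.0364) and Adgre1 (0.0387).

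Other splits of the same samples were counted for each comparison. The 10 splits of 3 against 3 libraries are too few for a share under 0.05, and the real split was the 1 with as many genes in each. Its count and the highest of the other splits were 620 and 40 from I to II in steady state, 4405 and 48 from II to III, 1176 and 31 from III to IV, 12 and 1, 11 and 0, and 3710 and 0 for the same steps under IL-33, and 518 and 4, 1023 and 0, 4256 and 0, and 1550 and 2 for stages I to IV of IL-33 against steady state. Libraries of 1 number deviated together in most steps between stages. The bar of 0.1 was missed from II to III in steady state (lowest 0.06) and from III to IV under IL-33 (lowest 0.05). In both of these steps all 6 libraries still lay closest to the library of their own number. The averaged effect, the interactions and the joint test were therefore split by moving the 4 libraries of a condition and number together, which leaves 10 splits as well. The real split was again the 1 with as many genes for the average (4855, the highest other 1), the interactions from II to III (842, the highest other 0) and from III to IV (2388, the highest other 0) and the joint test (2264, the highest other 0). For the interaction from I to II all 10 gave as many as the real 0, with 967 genes at an unadjusted p under 0.05 in edgeR, 103 genes called by DESeq2 and 37 by limma-voom. In 100 draws that exchanged single libraries within stages, 1 gave as many genes for the average (the highest other 1595), 6 and 1 for the later interactions (3858 and 1886), 2 for the joint test (2284) and 100 for the first interaction (270). Such draws treat libraries of a number as independent and turn part of the averaged effect into differences between steps, so no share was read from them.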

How the results depend on the processing

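The alternatives were planned except the share of unassigned reads as a covariate and leaving out the third steady state pool, which were chosen after seeing the data. Of 376 alternative values of the counts of genes and lists 301 lay within 1.5 times the reported count. Of 17681 values for 926 named gene results 16231 kept their side of the threshold, and their direction where called. A further 1020 lost the call, 426 gained one and 4, called in the main or the alternative fit, changed sign. Signs of results called in neither fit were not compared. Of 645 called gene results 298 lost the call under at least 1 alternative other than leaving out a library. The cause was not tested for the values below, unless fewer libraries or genes, or what the groups share in the fit, account for them by construction. Counts by DESeq2 were 1165 from I to II and 1822 from III to IV in steady state, 41 and 111 for the early IL-33 steps, 1078 and 1542 for stages I and II, and 103 and 1364 for the first 2 interactions. By limma-voom they were 905, 1089 and 6620 for the IL-33 steps, 2536 and 2693 for stages I and IV and 37 for the first interaction. With the replicate block they were 1069 from I to II in steady state, 24 and 93 for the early IL-33 steps, and 41 and 1391 for the first 2 interactions, and no other count moved past 1.5 times under the pairing. A fit of the compared groups alone gave 21, 1965 and 245 for the steady state steps, 678 from II to III under IL-33, 328 for stage I and 2 for the first interaction. No filter gave 39 from II to III under IL-33 and 12 for the first interaction, and the stricter filter 36. The unassigned share as a covariate gave 518 from III to IV in steady state, 4 from I to II under IL-33, 17, 310, 2224 and 189 for stages I to IV, and 258 for the average. Without the third steady state pool the early IL-33 steps gave 41 and 121 and the first 2 interactions 31 and 1664. No library of the IL-33 steps was left out there, so their counts moved through the filter, scaling and spread shared by the fit. With an estimated correlation 8, 15 and 11 list results passed for steady state steps, IL-33 steps and stages, against 44, 49 and 67 with the preset one and 51, 33 and 69 by fry's directional test. Among results called in the main or the alternative fit, log2 values that changed sign with the covariate were Mki67 in stage IV (0.033), and Atp5b (-0.047) and Cebpe (-0.255) in the average. Without the third pool it was Siglecf in the average (-0.326). Leaving out 1 library gave 289 to 675, 3566 to 4400 and 719 to 1230 genes for the steady state steps, 2 to 11, 0 to 5 and 2637 to 3086 for the IL-33 steps, 109 to 880, 381 to 1033, 3032 to 3897 and 802 to 1526 for stages I to IV, 4314 to 4962 for the average, 0 to 12, 4.6e+02 to 1177 and 1745 to 2419 for the interactions, 1667 to 2623 for the joint test, and 40 to 46, 47 to 52 and 62 to 71 list results. Depth limits genes of few reads. Simulated 2-fold changes were recovered in at most 26% of genes, in simulations that changed few genes and left out the IL-33 steps, the interactions and the average.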

Other observations

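The comparison of the overlap of steps below was chosen after the result was seen. Of the lists not given above for the averaged effect, 7 of synthesis, folding and energy metabolism were higher under IL-33 by camera, and none of these passed with an estimated correlation. Of 20 cholesterol synthesis genes 13 were higher, 14 adjusted over the list alone, with Fdps 3.5-fold (log2 1.80, SE 0.17, edgeR adjusted p = 2.96e-08) higher (adjusted p = 0.0648 with an estimated correlation), though Fdps was no longer called with the share of unassigned reads as a covariate, which is confounded with the condition. Of 24 endoplasmic reticulum folding genes 19 were higher and 1 lower, 19 and 2 adjusted over the list alone, with Canx 1.88-fold higher (adjusted p = 0.0648 with an estimated correlation). Of 52 cytosolic ribosomal protein genes 45 were higher, 46 adjusted over the list alone, with a median log2 fold change of 0.63 (adjusted p = 0.466 with an estimated correlation). Of 8 heme synthesis genes 5 were higher and 1 lower, also 5 and 1 adjusted over the list alone, with Fech, which inserts the iron, 2.83-fold higher (adjusted p = 0.293 with an estimated correlation). Of 18 glycolysis genes 10 were higher and 2 lower, 11 and 2 adjusted over the list alone (adjusted p = 0.312 with an estimated correlation), of 33 nuclear oxidative phosphorylation genes 10 were higher, 8 adjusted over the list alone (adjusted p = 0.686 with an estimated correlation), and of 25 ribosome biogenesis genes 15, also 15 adjusted over the list alone (adjusted p = 0.284 with an estimated correlation).

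Genes of lipid mediators, receptors and cytokines went both ways. Of 10 eicosanoid synthesis genes 3 were higher on average and 1 lower, also 3 and 1 adjusted over the list alone (adjusted p = 0.472 with an estimated correlation). Of 30 eosinophil surface receptors 4 were higher and 12 lower, 5 and 12 adjusted over the list alone (adjusted p = 0.257 with an estimated correlation), with Cd9 2.1-fold lower. Of 25 adhesion genes 2 were higher and 10 lower, the same adjusted over the list alone (adjusted p = 0.364 with an estimated correlation), and the complement receptor gene C3ar1 was 1 of the 2, 13.3-fold (log2 3.74, SE 0.42, edgeR adjusted p = 5.04e-07) higher. Of 18 cytokine genes 4 were higher and 9 lower, 4 and 10 adjusted over the list alone (adjusted p = 0.616 with an estimated correlation).

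Libraries of IL-33 stage III resembled earlier steady state stages. By correlation of log expression, 1 of the 3 was closest to the steady state mean of stage II and 2 to that of stage I, and of the IL-33 stage IV libraries 2 were closest to stage III and 1 to stage IV. The correlations of IL-33 stage III with stages I and II lay within 0.903 and 0.908. By edgeR's test IL-33 stage III differed from steady state stage I in 1581 genes, from stage II in 1065 and from stage III in 4256, and IL-33 stage IV from steady state stage III in 1382 and from steady state stage IV in 1550.

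A hypothesis is that part of the gene changes made between stages II and III in steady state, those of the cell cycle among them, falls between stages III and IV under IL-33. The 2 steps share no library. They shared 1160 genes called higher, where 287 would be if the lists were independent, and 1372 called lower, where 355 would be. Of 55 cell cycle genes 54 fell from II to III in steady state, 0 from II to III under IL-33 by edgeR and 53 from III to IV under IL-33. From II to III under IL-33, 684 of all 12743 genes had an unadjusted p under 0.05, near the share of 0.05 that no change would give. DESeq2 called 111 genes in that step and limma-voom 1089. As lists the cell cycle genes were already lower from II to III under IL-33 by camera. The median log2 fold change was -0.40 for S phase (adjusted p = 1.19e-07) and -0.19 for G2 and mitosis (adjusted p = 0.0357). With an estimated correlation neither list passed (adjusted p = 0.0697 and 0.558). The step from II to III under IL-33 also ran the same way as in steady state across genes, which are not independent replicates, with Spearman's rho 0.548 and Pearson's r 0.359, against 0.595 and 0.466 for the step from III to IV, and all 11 of its calls were shared, where 1.89 would be if independent. The overlap therefore does not place the changes in 1 step alone. The later fall of the cell cycle genes may mean that the sort markers and the transcripts are set apart under IL-33, which the deposited counts do not test.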
